A study of Homo sapiens with 9 samples.

How the data were processed

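The values came from 9 one-colour Affymetrix whole-transcript arrays of human prostate cancer tissue, 6 post-therapy and 3 pre-therapy. Per the labels' protocols, total RNA was isolated with the Qiagen miRNeasy Mini Kit and labelled with the GeneChip WT Terminal Labeling Kit. The deposited table held 33252 probe values per array, between 1.63 and 13.84. They were taken as log2 values from this range, since neither the labels nor the table header names a unit. The summarization software, the background correction and the normalization between arrays that the authors used are not given in the sources used here. Array medians of 5.64 to 5.72 differed by less than 0.2, so the deposited log2 values were tested without further normalization. The spread was not matched between arrays, with interquartile ranges from 1.94 on pre-therapy array 1 to 2.44 on post-therapy array 3. If the base of the logarithm were another, the fold values would change but the tests would not. The table had 0 columns of other samples.

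Genes were named from the platform annotation, which can be old. Of the probes, 19460 had 1 gene symbol, 1754 had several and 12038 had none named here. Probes with several symbols were not used to name genes. These probes gave 18417 genes. Symbols of 18387 genes were matched by gene identifier to a current reference table and 30 were kept from the array annotation. For the 769 genes with more than 1 probe, the probe with the highest mean over all 9 arrays was used, a rule that does not depend on the groups. Of 439 different genes placed by name in the lists, 390 were measured by such a probe and 49 were not analysed here.

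Groups and replicate numbers were taken from the sample labels. The labels call the samples biological replicates without naming donors, so p-values measure the spread between these samples. Pre-therapy and post-therapy samples share the numbers 1 to 3, with no statement that a number marks a patient, and the main model had no replicate block. The groups were compared with limma's lmFit and eBayes (limma 3.58.1 in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and no filter on dim probes. Gene lists with at least 5 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 32 lists. A list score of an array was the mean over the members of log2 values centred per gene on the mean of all 9 arrays. List scores were compared by an exact permutation test over all 84 splits into 6 and 3 arrays, two-sided, for which the smallest possible p is 0.0119.

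The lists were fixed before the data were examined. They covered T cell, cytotoxic effector, regulatory T cell, B cell, plasma cell, macrophage, dendritic cell, neutrophil and mast cell markers, inhibitory checkpoint and costimulatory genes, lymphoid chemokines, type I interferon and interferon gamma responses, and MHC class I and class II presentation. They also covered androgen receptor targets, androgen synthesis and receptor, lipid and sterol synthesis, cell cycle, luminal, basal and neuroendocrine epithelium, fibroblast and matrix, smooth muscle, endothelial, Schwann cell, red cell and platelet, immediate early and heat shock, hypoxia, small nucleolar RNA and ribosomal protein genes. The immunoglobulin segment and T cell receptor segment lists had fewer than 5 measured members and were not tested. Genes were named by a rule fixed at the same time. Part 1 took the 10 genes with the largest changes in each direction past the threshold, filled up by smallest p where fewer passed, so that here all were filled by smallest p. Part 2 took the 3 members of smallest p of each list described in detail, here the lists camera called. Both parts left out sex-linked genes of the Y chromosome and XIST, small RNA and unnamed loci, olfactory receptors and antigen receptor segments, and so named no small nucleolar RNA. Part 3 was a set of 14 genes of T cell checkpoints, T cells, macrophages and androgen signalling, of which 11 were measured.

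The gene and list tests were first checked on simulated data for the same 18417 genes, with 200 genes changed. For the comparison of all 9 arrays, limma recovered 37% of genes changed by 1 on the log2 scale and 83% of those changed by 2, and called 0.03% of unchanged genes. For post-therapy arrays 4 to 6 against pre-therapy it recovered 28% and 81% and called 0.04%. A simulated shift of 0.7 in the T cell list was called by camera in both designs. Its exact permutation p was 0.0119 over all 9 arrays and 0.1 for arrays 4 to 6 against pre-therapy. Simulated genes varied independently, whereas the estimated correlation among the real T cell markers was 0.645. The check therefore does not show how camera at a preset 0.01 behaves when members vary together.

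Alternatives chosen before the data were examined were quantile normalization, centring each array on its median, filters at the 25th and 50th percentile of mean signal, the mean of all probes of a gene, eBayes with a trend and robust settings, array weights, a replicate block, list scores as covariates, leaving out each array in turn, other thresholds and other tests. Alternatives added after seeing the data were leaving out post-therapy arrays 1 to 3, leaving out post-therapy arrays 4 to 6, and the small nucleolar RNA score as a covariate. Figures were drawn with Python 3.11.15.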

Results

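Total RNA of human prostate cancer tissue was measured on 9 whole-transcript gene expression arrays. Of these, 6 arrays held tumour tissue collected after leuprolide acetate plus ipilimumab and 3 held tissue collected before treatment. Leuprolide acetate is a gonadotropin-releasing hormone agonist that lowers testosterone, and ipilimumab is an antibody that blocks the T cell checkpoint receptor CTLA4. The samples were labelled as biological replicates, but the sources used here do not say whether pre-therapy and post-therapy tissue came from the same patients. Each array gave 33252 probe values, with array medians between 5.64 and 5.72 on the log2 scale, and 18417 genes were tested. The number of arrays limits the precision, and no measure of background signal was used.

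The 3 post-therapy arrays numbered 1 to 3 in the labels stood apart from the other 6 arrays. The first principal component, which held 54.3% of the variance across genes, separated them from the post-therapy arrays numbered 4 to 6 and from the pre-therapy arrays. Correlations across genes lay between 0.942 and 0.948 among arrays 1 to 3, between 0.917 and 0.971 among the other 6, and between 0.790 and 0.879 across the 2 sets. Small nucleolar RNAs, which guide the chemical modification of ribosomal RNA, were high on the same arrays. Their list score, the mean of the members' log2 values after centring each gene, was 1.06, 1.04 and 0.82 on arrays 1 to 3 and between -0.85 and -0.13 on the other 6. For this reason, the mean without post-therapy arrays 1 to 3 is given for each list that camera called.

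**Figure D1:**
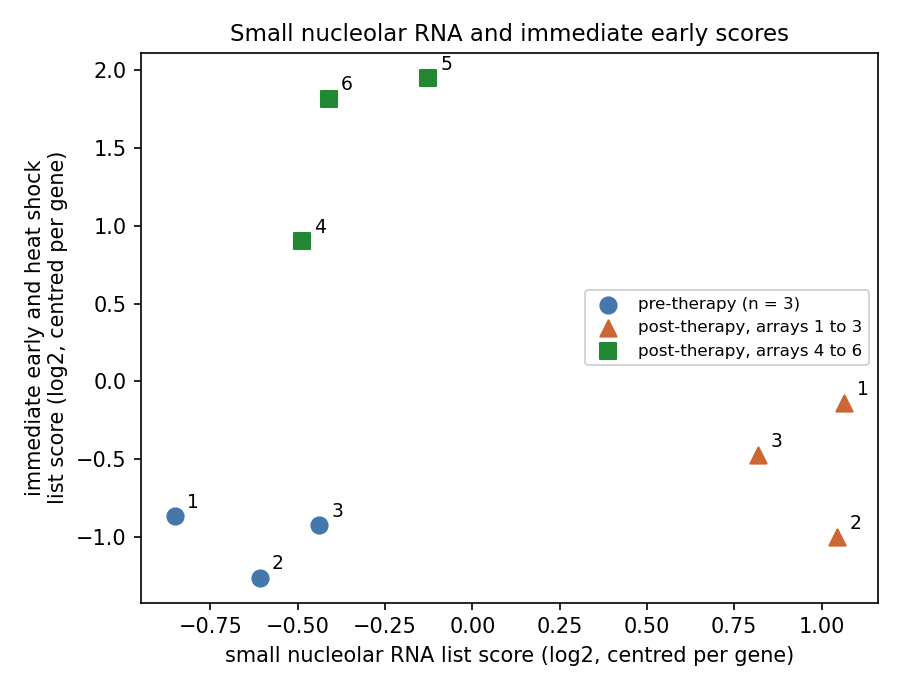
Small nucleolar RNA list score (x axis, log2, centred per gene) against immediate early and heat shock list score (y axis, log2, centred per gene) for each of the 9 arrays, numbered by replicate within group. Post-therapy arrays 1 to 3 have small nucleolar RNA scores of 0.82 or more, and post-therapy arrays 4 to 6 have immediate early scores of 0.90 or more.

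The comparison of the 6 post-therapy with the 3 pre-therapy arrays asked which genes and gene groups differed after the combined therapy. The 10 genes of smallest p among those higher after therapy did not pass limma after adjustment. CD69, an early activation marker of lymphocytes, was at 6.94 ± 0.84 (SD, n = 6) after and 4.02 ± 0.53 (SD, n = 3) before therapy, a log2 difference of 2.92 ± 0.46 (SE) or 7.55-fold. RGS1, a regulator of G protein signalling in lymphocytes, was higher by 3.49 ± 0.63 (SE), and CXCL10, an interferon-induced chemokine that attracts T cells, by 2.91 ± 0.49 (SE). SRGN, the proteoglycan of secretory granules in blood cells, was higher by 1.74 and ICOS, a costimulatory receptor of activated T cells, by 1.24. The others of the 10 were the kinase gene SGK1 (2.08), the gene of WEE1 (2.03), a kinase that delays entry into mitosis, NABP1 (1.64), the glucose transporter gene SLC2A3 (1.39) and the ubiquitin ligase gene PELI1 (1.20). Each of these 10 genes was higher on all 6 post-therapy arrays than on any pre-therapy array.

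At the other end, GLYATL1, an acyltransferase gene, was at 5.17 ± 0.27 (SD, n = 6) after and 7.06 ± 0.44 (SD, n = 3) before therapy, a log2 difference of -1.89 ± 0.23 (SE). TENM1, a teneurin gene, differed by -2.24, the vesicle GTPase gene RAB3B by -1.59, the angiotensin receptor gene AGTR1 by -1.37 and the transcription factor gene SOX14 by -1.20. EBP, an isomerase of cholesterol synthesis, differed by -1.15, AADAT, an aminotransferase of amino acid breakdown, by -1.14, PGAP6 by -1.10, the matrix peroxidase gene PXDN by -1.05 and the phosphatase gene PPM1E by -0.93. Each of these 10 genes was lower on all 6 post-therapy arrays than on any pre-therapy array. Across all genes, 343 were higher and 228 lower on every post-therapy array than on every pre-therapy array, together 3.10% of genes, where chance gives 2.38%.

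None of the 18417 genes passed a limma adjusted p under 0.05 over all 9 arrays. The smallest adjusted p was 0.0931, for GLYATL1, and that of CD69 was 0.318. At an unadjusted p under 0.05 limma gave 860 genes higher and 680 lower, where 921 in all were expected by chance. Without post-therapy arrays 1 to 3, limma gave 9 genes higher and 0 lower at adjusted p under 0.05 and 599 at unadjusted p. Without post-therapy arrays 4 to 6, which sets arrays 1 to 3 alone against pre-therapy, it gave 2653 higher and 3277 lower, and with the replicate block on replicates 1 to 3 it gave 5491. The arrays that stood apart make up the whole post-therapy group in both of these. Values of single genes given here for all 9 arrays are therefore differences that did not pass the test.

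Gene groups were compared through 34 lists chosen before the data were examined, of which 32 had at least 5 measured members. Of all 18417 genes, 7545 were higher and 10872 lower after therapy, with a median log2 difference of -0.08. Counts of higher and lower members are to be read against these. With limma's camera and its preset correlation between genes, 19 lists passed an adjusted p under 0.05, 16 higher and 3 lower after therapy. With an estimated correlation 0 lists passed, and 5 had an unadjusted p under 0.05. In the exact permutation test of list scores over all 84 splits of the arrays, two-sided, 11 lists had p under 0.05 and 0 passed after adjustment, with a smallest adjusted p of 0.127. Of the lists that camera called, the exact permutation p was above 0.05 for immediate early (0.0714), cytotoxic effector (0.0833) and regulatory T cell (0.0833) genes. It was also above 0.05 for type I interferon (0.0952), dendritic cell (0.107), ribosomal protein (0.107), androgen receptor target (0.119) and cell cycle (0.440) genes. For any list to pass after adjustment, many would have to lie at or near the smallest possible p, and 2 lists lay at it. Without post-therapy arrays 1 to 3, camera called 22 lists, and these included all 19 in the same direction, but 0 lists passed with an estimated correlation. The 3 added lists were neutrophil and basal epithelial markers, higher, and fibroblast and matrix genes, lower, at adjusted p of 0.417, 0.417 and 0.642 with an estimated correlation.

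Interferon response lists were higher after therapy by camera. All 13 measured members of the interferon gamma response list were higher after therapy, by a mean of 1.39 on the log2 scale, and the list passed camera at an adjusted p of 1.03e-13. Its adjusted p was 0.217 with an estimated correlation, and its exact permutation p was 0.0238. Over all genes 0 members passed limma, and 10 passed when adjusted over the list alone. CXCL10 and CXCL11, chemokines that attract T cells, were higher by 2.91 and 1.5, and IDO1, the enzyme that breaks down tryptophan, by 1.62. The score was higher on all 6 post-therapy arrays than on any pre-therapy array, and without post-therapy arrays 1 to 3 the mean difference was 0.92 and that of CXCL11 0.99. The transcript of interferon gamma itself, IFNG, lay at 3.92 ± 0.28 (SD, n = 6) after and 3.82 ± 0.38 (SD, n = 3) before therapy, below the median of every array. Of the type I interferon response list, 17 of 19 members were higher, with a mean of 0.73 and a camera adjusted p of 6.35e-08, or an adjusted p of 0.301 with an estimated correlation. OAS2, a sensor of viral RNA, was higher by 1.06, XAF1 by 1.22 and the antiviral GTPase gene MX1 by 0.91, and 2 members passed limma when adjusted over the list alone. The type I mean was 0.31 without post-therapy arrays 1 to 3, and XAF1 and MX1 were then higher by 0.70 and 0.60. With the small nucleolar RNA score as a covariate the type I mean was 0.18 and camera did not call the list, at an adjusted p of 0.0671.

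Of 12 chemokines of lymphoid cells 10 were higher after therapy, and the list mean was 1.11. The camera adjusted p was 2.74e-07, the adjusted p was 0.217 with an estimated correlation, and the exact permutation p was 0.0119, the smallest that the 84 splits can give. CCL5, a chemokine made by activated T cells, was higher by 1.83, and 8 members passed limma when adjusted over the list alone. The chemokine mean was 0.93 without post-therapy arrays 1 to 3. Of the MHC class I presentation list, 8 of 9 members were higher by a mean of 0.79, with a camera adjusted p of 1.43e-06, an adjusted p of 0.247 with an estimated correlation and an exact permutation p of 0.0119. B2M, the light chain of MHC class I, was higher by 1.49, the immunoproteasome subunit gene PSMB9 by 1.37 and the peptide transporter gene TAP1 by 0.95, and 3 members passed limma when adjusted over the list alone. All 10 measured members of the MHC class II list were higher, by a mean of 0.68, with a camera adjusted p of 4.85e-05 and an adjusted p of 0.247 with an estimated correlation. They included the protease gene CTSS (1.66), the peptide loading gene HLA-DMB (0.93) and the class II transactivator gene CIITA (0.40), and 0 passed limma when adjusted over the list alone. Without post-therapy arrays 1 to 3 the MHC class I and class II means were 0.54 and 0.58, and B2M, PSMB9, CTSS and HLA-DMB were higher by 0.69, 0.85, 0.86 and 0.51. HLA-DMB and CIITA were higher by 0.60 and 0.26 without pre-therapy array 2. Lists share members: CXCL10 and CXCL11 stand in the chemokine and the interferon gamma lists, and PSMB9 and TAP1 in the MHC class I and the interferon gamma lists. CCL5 is also a cytotoxic effector member, IDO1 stands in the inhibitory checkpoint and interferon gamma lists, and CIITA in the MHC class II and interferon gamma lists. Of the regulatory T cell list, CTLA4 and TIGIT are also inhibitory checkpoint members and ICOS is a costimulatory member. Calls of these lists are therefore not independent.

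Marker lists of several immune cell types were also higher by camera. All 19 measured T cell markers were higher after therapy, by a mean of 0.68, with a camera adjusted p of 4.60e-11, an adjusted p of 0.301 with an estimated correlation and an exact permutation p of 0.0476. The T cell receptor subunit genes CD3E, CD3G and CD3D were higher by 1.28, 1.13 and 0.87, CD4 by 0.79 and CD8A by 0.67, and 8 T cell markers passed limma when adjusted over the list alone. The T cell score was above every pre-therapy array on 5 of the 6 post-therapy arrays, and the mean difference was 0.50 without post-therapy arrays 1 to 3. Of the macrophage markers, 18 of 19 were higher by a mean of 0.92, with a camera adjusted p of 2.21e-12, an adjusted p of 0.279 with an estimated correlation and an exact permutation p of 0.0238. The mannose receptor gene MRC1 was higher by 1.74, the complement gene C1QA by 0.95, the signalling adaptor gene TYROBP by 0.94 and CD68 by 0.78, and 7 macrophage markers passed limma when adjusted over the list alone. The macrophage mean was 0.64 without post-therapy arrays 1 to 3 and 0.56 without pre-therapy array 2, whose macrophage score was -1.34. MRC1 was higher by 1.11 without post-therapy arrays 1 to 3, and TYROBP, CD68 and CD4 by 0.60, 0.31 and 0.53 without pre-therapy array 2.

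Camera called 4 further immune lists. Of the cytotoxic effector list, 12 of 17 members were higher by a mean of 0.43, with a camera adjusted p of 1.35e-03 and an adjusted p of 0.390 with an estimated correlation. Within it the granzyme gene GZMK was higher by 2.30 and the protease inhibitor gene CST7 by 0.68, whereas GZMB, the granzyme that triggers apoptosis of target cells, differed by -0.03 ± 0.25 (SE). Of the dendritic cell list, 10 of 15 members were higher by a mean of 0.29, with a camera adjusted p of 1.67e-03 and an adjusted p of 0.302 with an estimated correlation. LAMP3 and CD83, markers of mature dendritic cells, were higher by 1.02 and 0.58, and the lipid antigen presenting gene CD1E by 1.07. Of the regulatory T cell list, 6 of 10 members were higher by a mean of 0.32, with a camera adjusted p of 1.98e-03 and an adjusted p of 0.301 with an estimated correlation. Its members that passed limma when adjusted over the list alone were ICOS, CTLA4 and TIGIT, 3 receptors carried by activated T cells, while FOXP3, the defining transcription factor of regulatory T cells, was higher by 0.22 ± 0.20 (SE), or by 0.11 without pre-therapy array 2. Of 6 mast cell markers, 4 were higher by a mean of 0.49, among them the receptor kinase gene KIT (1.15), the carboxypeptidase gene CPA3 (1.14) and the histamine enzyme gene HDC (0.43). The camera adjusted p of the mast cell list was 6.04e-03, and its adjusted p was 0.301 with an estimated correlation. Without post-therapy arrays 1 to 3 the means were 0.34 for the cytotoxic effector, 0.33 for the dendritic cell, 0.37 for the regulatory T cell and 0.50 for the mast cell list, and GZMK was higher by 1.27. Without post-therapy arrays 4 to 6 camera did not call the dendritic cell, regulatory T cell and mast cell lists, at adjusted p of 0.141, 0.157 and 0.141. With a filter at the 25th percentile of mean signal it did not call the regulatory T cell and mast cell lists, at 0.0998 and 0.0509, and at the 50th percentile not the cytotoxic effector list, at 0.0516. The B cell, plasma cell and neutrophil lists had means of 0.20, 0.47 and 0.19 and did not pass camera, at adjusted p of 0.0947, 0.110 and 0.140. Without pre-therapy array 2, camera no longer called the cytotoxic effector, dendritic cell and regulatory T cell lists, whose means were then 0.32, 0.18 and 0.19. These calls moved with single arrays. The B cell and neutrophil lists passed camera without pre-therapy array 1 or post-therapy array 2, the plasma cell list without post-therapy array 2, and the B cell list without post-therapy array 6. The B cell and plasma cell means were 0.0853 and 0.14 without post-therapy array 3, and the neutrophil mean was 0.0360 without pre-therapy array 2. With quantile normalization the neutrophil list passed at an adjusted p of 0.0236, and with array weights the B cell list at 0.0483.

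Receptors and ligands that restrain T cells were compared as the inhibitory checkpoint list. Of its 20 measured members 12 were higher, by a mean of 0.35, with a camera adjusted p of 2.95e-04, an adjusted p of 0.301 with an estimated correlation and an exact permutation p of 0.0476. CTLA4, the target of ipilimumab, was at 5.77 ± 0.44 (SD, n = 6) after and 4.53 ± 0.17 (SD, n = 3) before therapy, a log2 difference of 1.24 ± 0.25 (SE) or 2.36-fold, with a limma adjusted p of 0.509. CD96, a receptor of T and NK cells, was higher by 1.5, TIGIT by 0.47 and CD274, the gene of the PD-L1 ligand, by 0.53 ± 0.23 (SE). VSIR, the gene of the VISTA checkpoint, was at 6.16 ± 0.26 (SD, n = 6) after and 5.86 ± 0.10 (SD, n = 3) before therapy, a difference of 0.30 ± 0.18 (SE) with a limma adjusted p of 0.518. CD96 and CD274 were higher by 0.92 and 0.31 without post-therapy arrays 1 to 3. CTLA4, TIGIT and CD274 were higher on all 6 post-therapy arrays than on any pre-therapy array, and VSIR on 4 of 6. Passing limma when adjusted over the list alone were 4 members, namely CTLA4, IDO1, CD96 and TIGIT. The mean of the checkpoint list was 0.33 without post-therapy arrays 1 to 3, and 0.38 without post-therapy arrays 4 to 6, where camera did not call it at an adjusted p of 0.0657. It was 0.23 without pre-therapy array 2. Of 15 costimulatory genes 9 were higher by a mean of 0.34, with a camera adjusted p of 3.25e-03 and an adjusted p of 0.301 with an estimated correlation. Besides ICOS, which alone passed limma when adjusted over the list, CD27 was higher by 1.14 and CD226 by 0.95. The costimulatory mean was 0.25 without post-therapy arrays 1 to 3, and CD226 was then higher by 0.49. Camera did not call the list without pre-therapy array 2, at a mean of 0.23, without post-therapy arrays 4 to 6, at an adjusted p of 0.0666, or with the 25th percentile filter, at 0.0621.

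**Figure D2:**
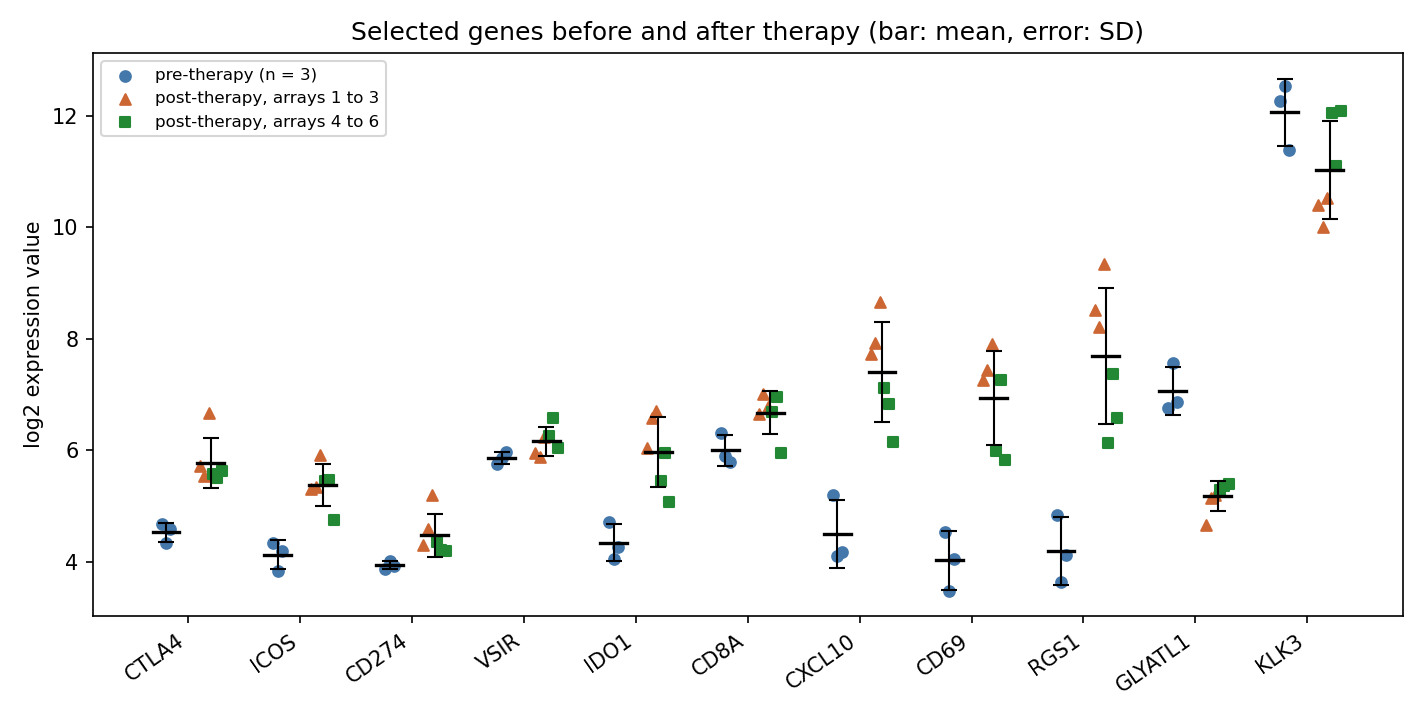
Log2 expression value (y axis) of 11 genes on each pre-therapy array (n = 3) and post-therapy array (n = 6), where bars are group means, error bars SD and symbols single arrays. CTLA4 has means of 4.53 before and 5.77 after therapy, CXCL10 means of 4.49 and 7.40, and GLYATL1 means of 7.06 and 5.17, while VSIR has means of 5.86 and 6.16.

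The lists of androgen receptor targets and of lipid and sterol synthesis were lower after therapy by camera. Of 22 measured androgen receptor targets 19 were lower, by a mean log2 difference of -0.62, with a camera adjusted p of 1.46e-03, an adjusted p of 0.403 with an estimated correlation and an exact permutation p of 0.119. PMEPA1 differed by -1.92, TPD52 by -1.12 and the kinase gene CAMKK2 by -0.77. KLK3, the gene of prostate-specific antigen, was at 11.02 ± 0.88 (SD, n = 6) after and 12.06 ± 0.60 (SD, n = 3) before therapy, a difference of -1.03 ± 0.48 (SE). Without post-therapy arrays 1 to 3 the difference of KLK3 was -0.32, that of PMEPA1 was -1.20 and the list mean was -0.38. With the small nucleolar RNA score as a covariate the KLK3 difference turned to 0.0691. Without pre-therapy array 2 the list mean was -0.40 and camera no longer called it, at an adjusted p of 0.0931. All 15 measured genes of lipid and sterol synthesis were lower, by a mean of -0.79, with a camera adjusted p of 2.26e-05, an adjusted p of 0.301 with an estimated correlation and an exact permutation p of 0.0238. The fatty acid desaturase genes FADS2 and SCD differed by -2.06 and -1.62, and DHCR7, an enzyme of cholesterol synthesis, by -1.16. FADS2 lay at 7.30, 9.99 and 9.87 on pre-therapy arrays 1, 2 and 3, and only 2 of 6 post-therapy arrays lay below all of these. In neither list did a member pass limma when adjusted over the list alone, and 7 androgen receptor targets and 8 lipid synthesis genes were lower at an unadjusted p under 0.05. The lipid synthesis mean was -0.72 without post-therapy arrays 1 to 3. It was -0.56 without pre-therapy array 2, where camera still called the list at an adjusted p of 0.0117.

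Cell cycle genes were lower in 23 of 25 members, by a mean of -0.31, with a camera adjusted p of 0.0118 and an adjusted p of 0.611 with an estimated correlation. The mitotic kinase genes PLK1 and AURKB differed by -0.88 and -0.61 and the replication licensing gene MCM2 by -0.42. This difference rested on pre-therapy array 3, whose cell cycle score was 1.15. Without that array the list mean was 0.15 in the other direction, with a camera adjusted p of 0.0359, and without pre-therapy array 2 it was -0.61. PLK1, AURKB and MCM2 differed by -0.20, -0.23 and -0.26 without pre-therapy array 3. The call was also lost when post-therapy array 4, 5 or 6 was left out in turn and when all 3 were left out. The mean was -0.45 without post-therapy arrays 1 to 3, with AURKB at -0.40 and MCM2 at -0.23. Genes of androgen synthesis and the androgen receptor differed by a mean of -0.16 and did not pass camera, at an adjusted p of 0.314, and the mean was -0.0954 without post-therapy array 3.

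**Figure D3:**
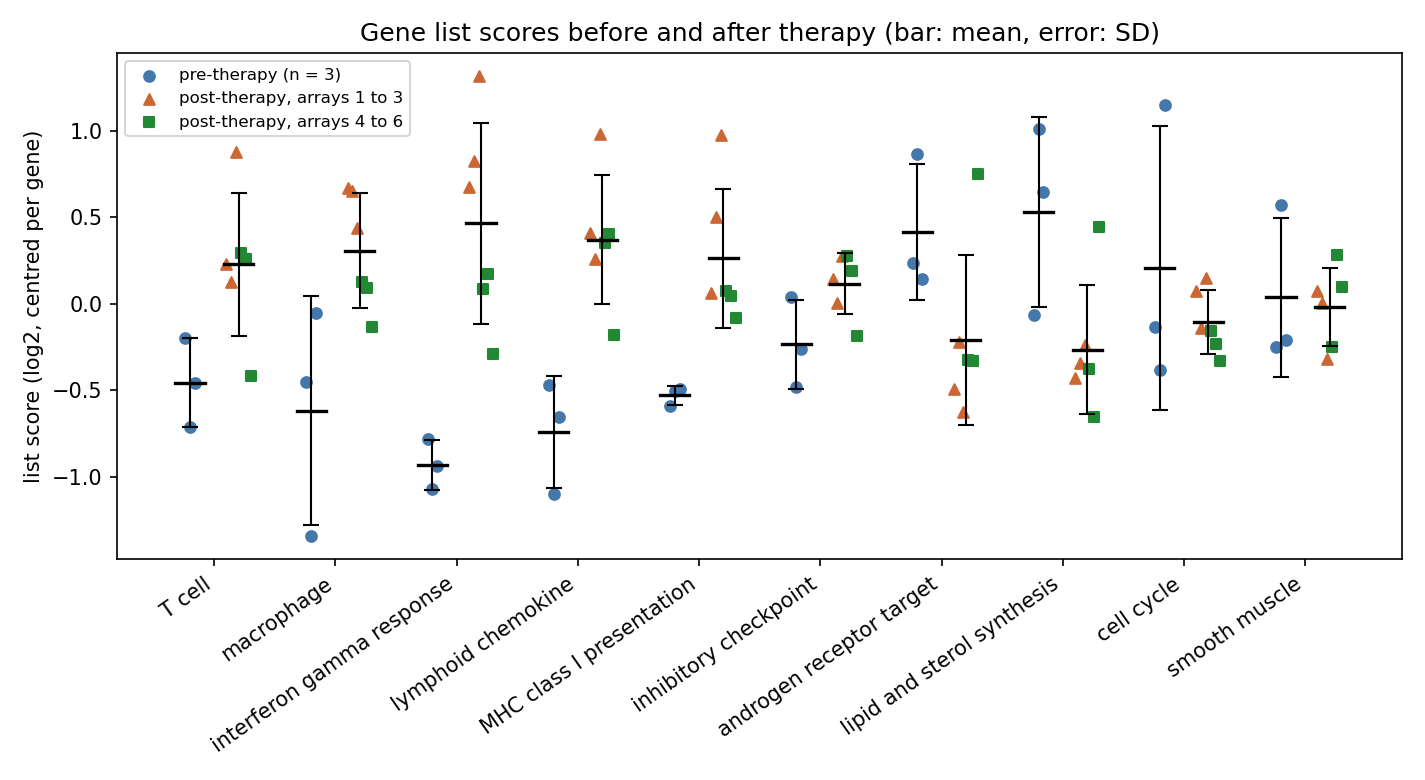
List score (y axis, mean log2 value of the members after centring each gene) of 10 gene lists on each pre-therapy array (n = 3) and post-therapy array (n = 6), where bars are group means, error bars SD and symbols single arrays. The interferon gamma response means are -0.93 before and 0.46 after therapy, and the androgen receptor target means are 0.41 and -0.21.

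Markers of epithelium and stroma did not pass camera over all 9 arrays. The luminal epithelial list had a mean difference of -0.26 with an adjusted p of 0.0947, and the basal epithelial list a mean of 0.19 with an adjusted p of 0.263. The basal epithelial mean was 0.0396 without post-therapy array 5 and 0.10 without pre-therapy array 1. The luminal list passed camera without pre-therapy array 1, at a mean of -0.33, and without post-therapy array 6, at a mean of -0.39, while the mean was -0.16 without post-therapy array 2. It also passed with quantile normalization and with the 25th and 50th percentile filters, at adjusted p of 0.0420, 0.0494 and 0.0350, and its mean was -0.0073 without post-therapy arrays 1 to 3 and 0.0602 with the small nucleolar RNA score as a covariate. The means were -0.02 for neuroendocrine, -0.03 for endothelial and -0.0035 for fibroblast and matrix genes, with adjusted p of 0.904, 0.999 and 0.999. Without pre-therapy array 2 camera called fibroblast and matrix genes lower, at a mean of -0.40, and smooth muscle genes higher, at a mean of 0.21 and an adjusted p of 0.0175. The smooth muscle list had a mean of -0.06 but a median of 0.03, and its adjusted p over all 9 arrays was 0.999. Schwann cell markers had a mean of -0.23, red cell and platelet genes -0.22 and hypoxia genes -0.02, with adjusted p of 0.206, 0.259 and 0.999, and all 3 means changed sign with the small nucleolar RNA covariate.

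Immediate early genes, which are induced within minutes of a stimulus, were higher in all 16 measured members of their list, by a mean of 1.53. The camera adjusted p was 1.35e-10, the adjusted p was 0.301 with an estimated correlation, the exact permutation p was 0.0714, and 3 members passed limma when adjusted over the list alone. NR4A2, a nuclear receptor gene, was higher by 2.11, CCN1, a matrix protein gene, by 2.15 and DUSP1, a phosphatase gene, by 2.05. The list mean was 2.57 without post-therapy arrays 1 to 3. The list score was 0.90, 1.95 and 1.82 on post-therapy arrays 4, 5 and 6, between -1.0 and -0.14 on post-therapy arrays 1 to 3 and between -1.26 and -0.87 before therapy. The 9 genes that limma called without post-therapy arrays 1 to 3 were all members of this list. They rose by log2 values from 2.56 for NR4A3 to 4.08 for FOS, with CCN1 at 3.01 and an adjusted p of 1.79e-03, and were EGR1, NR4A1, NR4A2, FOSB, DUSP1 and ZFP36 besides. Those outside the fixed rule for named genes are given because they passed that test. Of 176 small nucleolar RNAs 161 were higher by a mean of 0.95, with a camera adjusted p of 3.87e-28, an adjusted p of 0.283 with an estimated correlation and a mean of 0.29 without post-therapy arrays 1 to 3. Of 64 ribosomal protein genes 50 were higher by a mean of 0.32, with a camera adjusted p of 6.35e-08 and an adjusted p of 0.302 with an estimated correlation. RPL11, RPS27 and RPS3 were higher by 1.07, 1.04 and 0.53, or by 0.63, 0.53 and 0.47 without post-therapy arrays 1 to 3, and the ribosomal protein mean was then 0.12. With the small nucleolar RNA score as a covariate it was 0.0171 and camera did not call the list, at an adjusted p of 0.613.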

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

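Of the tests in this part, those of other small RNAs, of immune against stromal markers, of the interferon gamma and T cell lists without arrays 1 to 3, and of T cell content were chosen only after the result was seen. Chance could not be excluded for the count of genes at unadjusted p or the count of lists over all 9 arrays. At an unadjusted p under 0.05, 15 of the 84 splits into 6 and 3 arrays gave as many as the real 1540 genes, and the highest other gave 9475. As many lists as the real 19 were called in 16 of 84 splits, and the highest other split called 25. Limma called 0 genes at adjusted p in the real split, a count that all 84 splits reach by construction, so it tests nothing about chance, and the highest other split gave 7767. The split with 7767 genes set post-therapy arrays 1 to 3 against the other 6 arrays, which points to a structure of the samples other than the therapy groups. For post-therapy arrays 4 to 6 against pre-therapy, 1 of the 10 splits, the real one, gave 9 genes and the highest other gave 0, and 10 splits are too few to exclude chance.

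Post-therapy arrays 1 to 3 had small nucleolar RNA signal above the other 6 arrays. Scaling between arrays was argued against, since the median gap of 176 small nucleolar RNAs was 1.17 on the log2 scale after quantile normalization. Other small RNAs outside the list, namely small nuclear, Cajal body and vault RNAs, were higher on the same arrays by a median of 1.14, with 43 of 48 higher, while protein-coding genes had a median gap of -0.14. MicroRNA genes went the other way, with a median gap of -0.26 and 39 of 173 higher. A difference in the recovery or labelling of the small RNA classes that were higher is a candidate explanation. The labels give no batch to test it against. A biological difference among the post-therapy tumours stays open as untested.

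Interferon gamma, T cell and macrophage lists were higher after therapy by camera, but did not pass with an estimated correlation, at adjusted p of 0.217, 0.301 and 0.279. A lower share of epithelium that raised all other cells alike would raise stromal markers too. The immune minus stromal score was higher after therapy by 1.08 (exact permutation p = 0.0119, two-sided, the smallest the splits can give). Its lists were picked after their differences were seen, so this p is no test of that explanation. Immune cells in the place of epithelium would also leave stromal markers unchanged, so a lower share of epithelium stays open. Post-therapy arrays 1 to 3 as the only source were argued against for the interferon gamma list, whose score difference without them was 0.92 ± 0.163 (SE), with no overlap between groups. This does not exclude chance, since the list was picked after its difference was seen. Without those arrays its camera adjusted p with an estimated correlation was 0.0730. For the T cell list the difference without them was 0.50 ± 0.275 (SE), within 2 standard errors of 0, so a contribution of those arrays alone cannot be told apart from therapy with 3 arrays a group. More immune cells or stronger interferon signalling after therapy stay as hypotheses, since 16 of 84 splits called as many lists.

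Immediate early genes were high on post-therapy arrays 4 to 6. Scaling was argued against by a score difference to pre-therapy of 2.56 after quantile normalization. T cell content was argued against, because arrays 1 to 3 had a T cell score higher by 0.37 ± 0.330 (SE) than arrays 4 to 6 but an immediate early score that differed by -2.09 ± 0.415 (SE). Time without blood supply before RNA isolation may raise these genes and cannot be told apart from therapy here: the hypoxia score differed by 0.12 ± 0.255 (SE), and no label gives handling times. A response of the tissue to therapy stays open as untested.

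In 10 of 107 genes and list scores examined, 1 post-therapy array lay far from the other 5, and chance marks about 1 in 20. Array 1 had the lowest GLYATL1 value, 4.66, where the nearest other was 5.15. Array 4 had the highest PPM1E value, 4.82, where the nearest other was 4.37. Array 6 had the lowest CCL5 value, 6.56, against 7.87 or more on the others, and without this array CCL5 passed limma at an adjusted p of 0.0478. It also had the lowest CD8A value, 5.94, the highest androgen receptor target score, 0.75, and the highest hypoxia score, 0.52. On array 3 the CTLA4 value was 6.66, against 5.71 or less on the other 5, the CD27 value 8.14 and the plasma cell score 1.78. The plasma cell list mean was 0.47 with array 3 and 0.14 without it. Array 5 had a basal epithelial score of 0.83, where the nearest other was 0.09.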

How the results depend on the processing

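The alternatives without post-therapy arrays 1 to 3 or 4 to 6 and with the small nucleolar RNA covariate were added after the data were seen. For genes, limma called 0 with median centring, both signal filters, probe means, trend and robust eBayes, and each of the 3 covariates, and Welch's test called 0 (1842 at unadjusted p). Limma called 1 with quantile normalization, 1 with the random replicate block and 1 at an adjusted p under 0.1 (GLYATL1 in each), 5 with array weights, 9 without post-therapy arrays 1 to 3, 5930 without post-therapy arrays 4 to 6, and 0 to 1 without each array in turn (CCL5, without post-therapy array 6). At unadjusted p there were 1540, of which 1140 were at least 1.5-fold. Same-numbered arrays, centred on their group means, correlated at -0.13, 0.17 and 0.14. The consensus correlation of the random replicate block was 0.16. With so few arrays, these values cannot tell whether a shared number marks a patient. With the replicate block on replicates 1 to 3 limma called 5491 genes and camera 14 lists. That block uses post-therapy arrays 1 to 3 alone, as does leaving out arrays 4 to 6. Of the lists, camera called 13 to 22 in all alternatives but 2, and both an estimated correlation and fry called 0. The exact permutation test called 0 with both other scalings, both filters, probe means, member medians and each array left out, with smallest adjusted p from 0.0571 to 0.421. These counts of 0 are weak evidence, since many lists would have to lie at or near the smallest possible p for any to pass. Without arrays 1 to 3 or 4 to 6 the smallest possible p of the test is 0.1, so no list could pass there. The test was not run with array weights, trend and robust eBayes, blocks or covariates. Under the estimated correlation and fry the means stayed at 0.68 for T cell, 0.92 for macrophage, 1.39 for interferon gamma, 0.35 for inhibitory checkpoint and -0.62 for androgen receptor targets, and the adjusted p were from 0.0644 to 0.403. These lists range without each array from 0.55 to 0.81, 0.56 to 1.20, 1.22 to 1.54, 0.23 to 0.49 and -0.81 to -0.40. The checkpoint list was at 0.38 and not called both under the replicate block and without arrays 4 to 6. Other calls also moved. The replicate block lost the regulatory T cell, dendritic cell, mast cell, costimulatory and cell cycle lists and added luminal. The small nucleolar RNA covariate lost the type I interferon and ribosomal protein lists and, since it removes that score, the small nucleolar RNA list. It added neutrophil, higher, and fibroblast, lower, and neuroendocrine and endothelial, higher, at adjusted p of 0.0173 and 0.0476. Fewer than 5 members were left in 3 lists at the 25th percentile filter and in 10 at the 50th, which were not tested there. The cell cycle list changed sign without pre-therapy array 3. Lists with a main mean within 0.06 of 0 changed sign in several alternatives, and luminal, Schwann cell and red cell lists, at -0.26, -0.23 and -0.22, with the small nucleolar RNA covariate, red cell also without arrays 1 to 3. Quantile normalization gave neuroendocrine 0.0334, the 25th percentile filter neuroendocrine 0.0365, and the 50th percentile filter endothelial 0.0529 and hypoxia 0.0053. Fibroblast genes were at 0.0570 with array weights, 0.0450 with the random block, and 0.31 both under the replicate block and without arrays 4 to 6. The luminal covariate gave neuroendocrine 0.0118, smooth muscle 0.0134, endothelial 0.0059, hypoxia 0.15 and IFNG -0.0509. The small nucleolar RNA covariate gave luminal 0.0602, neuroendocrine 0.21, endothelial 0.15, Schwann cell 0.0012, red cell 0.10, hypoxia 0.13, GZMB 0.28 and KLK3 0.0691. Without arrays 1 to 3, neuroendocrine was at 0.14, smooth muscle 0.0047, endothelial 0.12, red cell 0.0287, hypoxia 0.12 and GZMB 0.15. Without each array in turn, the ranges were -0.61 to 0.15 for cell cycle, -0.15 to 0.0360 for endothelial, -0.40 to 0.20 for fibroblast, -0.18 to 0.0891 for hypoxia, -0.0877 to 0.0404 for neuroendocrine, -0.20 to 0.21 for smooth muscle, -0.15 to 0.0918 for GZMB and -0.0371 to 0.31 for IFNG. The cause of these changes was not tested, except that camera with an estimated correlation allows for members that vary together. Over all alternatives, 8 of 1697 values of 75 named genes and 41 of 819 values of 32 lists reversed. No background measure was used, so limits for dim genes such as IFNG, CD274, TIGIT and ICOS are unknown.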

Other observations

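Outside the lists, further genes at small unadjusted p in limma, none past the adjusted threshold, are given as values chosen after they were seen. CXCR4, a chemokine receptor of leukocytes, was higher after therapy by 2.15 ± 0.49 (SE), CYTIP by 2.58 ± 0.60 (SE), and LCP2, an adaptor of T cell receptor signalling, by 1.42 ± 0.30 (SE). NFKBIZ, a regulator of NF-kappa-B target genes, was higher by 1.72 ± 0.37 (SE), BHLHE40 by 1.25 ± 0.26 (SE) and MCL1, an inhibitor of apoptosis, by 1.16 ± 0.24 (SE). SERPINB9, an inhibitor of granzyme B, was higher by 1.33 ± 0.30 (SE), beside GZMB at -0.03. Each of these genes but GZMB was higher on all 6 post-therapy arrays than on any pre-therapy array.

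Of 14835 probes outside the gene test, limma called 0 at an adjusted p under 0.05, with a smallest adjusted p of 0.526, and 1008 had an unadjusted p under 0.05. On post-therapy arrays 1 to 3, the 40 small nucleolar RNAs of the SNORD115 and SNORD116 families were higher than on the other 6 arrays by a median of 1.13. These 40 are part of the 176 small nucleolar RNAs of the list. On the same arrays, 64 ribosomal protein genes were higher by a median of 0.37. The 173 microRNA genes differed by a median of -0.26, with 39 higher.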
